A study of Arabidopsis thaliana with 6 samples.

How the data were processed

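RNA sequencing of whole leaves of Arabidopsis thaliana Col-0 was done on 6 samples, 3 from plants grown at 380 ppm CO2 and 3 from plants grown at 100 ppm CO2. Per the labels' protocols, total RNA was isolated with a column kit (PureLink) and libraries were made with the Illumina TruSeq RNA kit, version 2. The labels number the replicates in each group, and nothing in them says that the same number marks shared plants or a shared day. The submitters' processing notes name FastQC, TopHat and Cufflinks, with no versions. The genome build, the annotation, the way reads were counted, the use of strand and the pooling of replicates were not given in the sources used here.

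The deposited table holds RPKM values made by the authors, in 2 columns named for the CO2 levels. Each column was treated as the authors' value for its group, with no SD and no n. The labels name 3 samples per CO2 level and the columns name none of them, so whether a column pools 3 libraries or holds 1 library cannot be read from the column names. The table lists 26402 genes by locus, of which 5392 were at 0 in both columns, 5949 at 0 at normal CO2 and 6320 at 0 at low CO2.

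Whole reads were recovered from the RPKM values. Each value was taken as proportional to reads / (depth × length), with the coding length of the locus in the reference less the 3 bases of the stop codon, and the depth of each column was searched until the values gave whole reads. Of 21010 genes above 0 in either column 20247 (96.4%) gave whole reads in both columns within 0.0001 reads, against 1.47% when the stop codon was kept in the length. The depths were 25429325 reads at normal CO2 and 21887516 at low CO2, and the recovered reads made up 95.5% and 95.1% of them. A mean of 3 separately scaled libraries, tested on simulated data, put 2.17% of 19899 genes on such a grid, so each column derives from 1 set of reads, pooled or single. At these depths 1 read on 1 kb of coding length is worth 0.0393 RPKM at normal CO2 and 0.0457 at low CO2, and a floor of 3 reads 0.118 and 0.137 RPKM.

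Names, products and coding lengths were taken from the RefSeq annotation of the assembly TAIR10.1. It was used for nothing else, and no coordinates are given because the authors' build is not stated. Of the listed loci 25802 matched the reference, 600 did not, and 10061 had a symbol there. A gene without a symbol is named by its locus. Where no strand is known, reads of overlapping and antisense genes cannot be told apart, and near-identical copies (RBCS, LHCB1, LHCB2, CYP79F, TGG and the phosphoglycolate phosphatase pair) can share reads.

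A limma test of 3 against 3 samples on log2(RPKM + 1), with camera tests of gene lists, had been planned before the data were examined. Neither could be run, because the table holds 1 column per group and no columns of single replicates. In their place, differences are given as log2((RPKM at low CO2 + 1)/(RPKM at normal CO2 + 1)) for genes with a mean of at least 1 RPKM, with a size rule of 2-fold, and as plain RPKM ratios for named genes. The ratio's 95% interval is the exact Clopper-Pearson interval of the low CO2 share of a gene's recovered reads, scaled by the depths. It covers counting error only, compares these columns and not the conditions, and could not be given for the 468 counted genes without recovered reads. Plastid genes were among those.

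The text describes 27 gene lists with 416 entries, which had been fixed by locus before the data were examined. Of the entries 402 were in the table, 14 were not analysed here, and 367 were counted. For 397 entries the reference gives the fixed symbol. The median log2 ratio of a list was set against 10000 random lists of the same size, drawn within 20 bins of mean RPKM, and a percentile above 97.5 or below 2.5 was read as standing apart. The percentile describes these columns and is not a test of the CO2 effect.

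The genes named were chosen by a rule written before the data were examined. It took the 10 largest log2 differences each way among genes of at least 5 RPKM in the higher column, up to 4 members of each list with the largest differences, or the 2 most abundant members where none passed, and 12 fixed genes. The part on list members had asked for a test, which the size rule of 2-fold replaced, and the largest differences were ranked on the RPKM + 1 scale. Genes named outside the rule are said to have been chosen after their values were seen. An exact 0 can be a failed estimate: the pathway gene F3H and NDHL, a nuclear gene of the cyclic electron flow list, were listed at or near 0. A gene at 0 is therefore described as listed at 0 or set against the floor.

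The read recovery, the size rule and the list percentiles were tested on simulated data for low against normal CO2. The depths came back exactly and 100% of 20137 genes gave back their reads. Of 50 genes drawn at 2-fold higher 28% passed the 2-fold rule, and of 50 drawn at 4-fold higher 100% did. For genes drawn lower, 28% of 50 passed at 2-fold and 94% of 50 at 4-fold. Of 200 random lists of 20 genes 4.5% fell outside the percentile band, a share set by how the band is drawn. Of 200 lists shifted by 0.5, 100% fell above it. Both simulated columns came from the normal CO2 profile, so log2 ratios of unchanged genes held counting error only. In the real columns the SD of the log2 ratios was 0.893, so the 100% does not carry over to them. Alternatives tried were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 RPKM, quantile normalization and median scaling. Size rules of 1.5-fold and 4-fold, read and interval filters, nuclear genes only and removal of a trend over GC content and coding length were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.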

Results

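Whole leaves of Arabidopsis thaliana Col-0, a plant with C3 photosynthesis, were profiled by RNA sequencing after growth at 100 ppm CO2 (low CO2) or 380 ppm CO2 (normal CO2). The 6 samples formed 2 groups of 3, taken from plants 4 weeks old that had grown under 16 h light and 8 h dark at 21 °C and 70% relative humidity. The deposited table gave an RPKM value (reads scaled to the length of the gene model and to the depth) for 26402 genes, with 1 column per CO2 level and none for a single replicate. The reads behind the columns were recovered from the values, with a depth of 25429325 reads at normal CO2 and 21887516 at low CO2. Without replicate values no difference between the columns had a replicate check and no test of the CO2 effect was made. Ratios are therefore given as low over normal CO2 with 95% intervals that cover counting error only.

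The comparison of both columns asked which leaf transcripts differed after growth at low CO2, in a series concerned with low CO2 and the evolution of C4 photosynthesis. DIN10 and BT2, genes that plants deprived of sugar express strongly, had the largest log2 differences upward at low CO2. DIN10 (AT5G20250), a raffinose synthase family gene of the dark-inducible set, stood at 5.57 RPKM at normal CO2 and 736 RPKM at low CO2, 132-fold higher (118 to 148). BT2 (AT3G48360), a BTB and TAZ domain gene, was at 0.468 and 135 RPKM, 288-fold higher with an interval of 168 to 541 because only 13 reads lay behind the normal CO2 value. Defence and pigment genes were among the 10 genes with the largest log2 difference downward. The pathogenesis-related gene PR1 (AT2G14610) was at 245 RPKM at normal CO2 and 3.12 RPKM at low CO2, 78.5-fold lower (55.8 to 114), and LDOX (AT4G22880), an enzyme of anthocyanin synthesis, was 82.5-fold lower (63.5 to 109).

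Of 16563 genes with a mean of at least 1 RPKM, 1006 (6.07%) were at least 2-fold higher at low CO2 and 1834 (11.1%) at least 2-fold lower on the log2(RPKM + 1) scale, which understates the difference of low genes. The other 13723 genes (82.9%) lay within 2-fold, and the median log2 ratio of all counted genes was -0.06. At least 8-fold differences were seen for 80 genes higher and 154 lower at low CO2. The whole counting interval of the ratio lay beyond 2-fold for 813 genes higher and 1532 lower. A gene counted had a median of 588 reads at normal CO2 and 474 at low CO2.

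**Figure D1:**
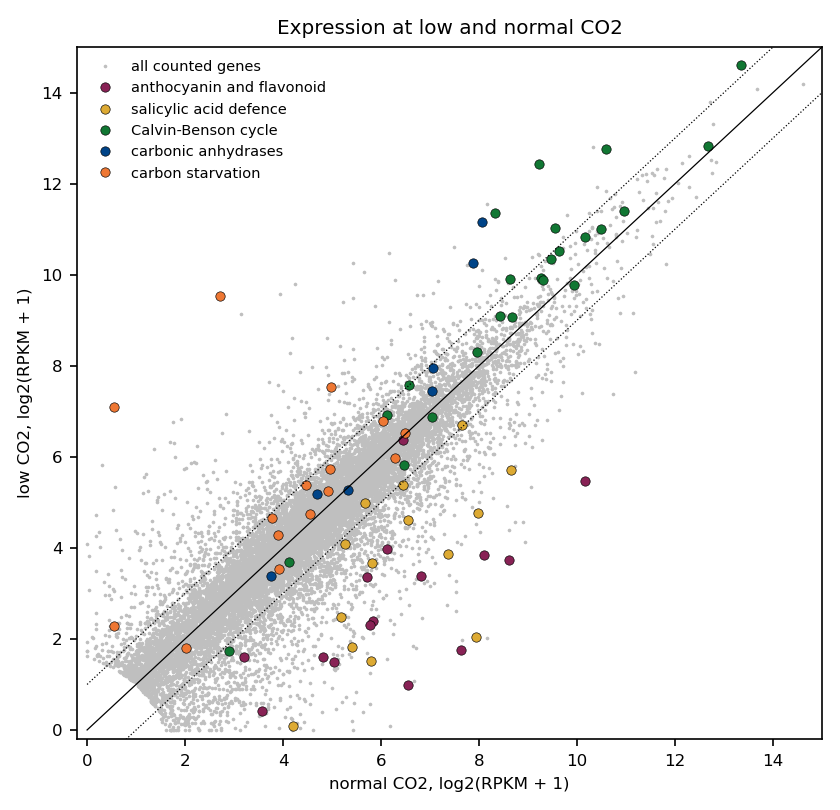
Expression of each counted gene as log2(RPKM + 1) at normal CO2 (x axis) and low CO2 (y axis), with grey points for all 16563 counted genes and coloured points for members of 5 gene lists; the solid line marks equal values and the dotted lines a 2-fold difference. Of the counted genes 1006 lie on or above the upper dotted line and 1834 on or below the lower one.

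Among the 10 genes with the largest log2 difference upward, GASA6 (AT1G74670), a gibberellin-regulated gene, was at 14.3 and 760 RPKM, 53.2-fold higher at low CO2 (44.1 to 64.9). The homeodomain-like gene RVE2 (AT5G37260) was 45.5-fold higher (34.6 to 61.1) and COL9 (AT3G07650), a CONSTANS-like gene, 45.1-fold higher (33.5 to 62.0). AT5G62360, of the invertase and pectin methylesterase inhibitor family, was 71.7-fold higher (59.9 to 86.5), and the HSP20-like gene AT4G21870 was 49.6-fold higher (42.8 to 57.7). The chaperone DnaJ-domain gene AT1G72416 stood at 41.8 and 1215 RPKM, and the aspartyl protease gene AT5G19120 at 2.75 and 113 RPKM. AT4G33980, whose product the reference lists as uncharacterized, was 231-fold higher, but its interval ran from 89.7 to 849 because 4 reads lay behind its normal CO2 value.

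The genes with the largest log2 difference downward included TAT3 (AT2G24850), a tyrosine aminotransferase, at 285 and 3.05 RPKM and 93.7-fold lower at low CO2 (76.1 to 117). NATA1 (AT2G39030), an N-acyltransferase, was at 71.5 RPKM at normal CO2 and had 1 read at low CO2, a ratio of 1071-fold lower with an interval of 192 to 42325. The Kunitz trypsin inhibitor gene KTI1 (AT1G73260) had 687 reads at normal CO2 and was listed at 0 at low CO2. Set against a floor of 3 reads it was 197-fold lower. The counting interval of its ratio reached up to 0.00626, a weaker bound than the floor gives, and a value listed at 0 can be a failed estimate. PAP1 (AT1G56650), a regulator of anthocyanin synthesis, was 94.0-fold lower (57.7 to 165) and GRX480 (AT1G28480), a glutaredoxin of the thioredoxin superfamily, 90.8-fold lower (49.2 to 190). The gene DIP2 (AT5G03210) was 67.4-fold lower (38.4 to 131) and the glycosyl hydrolase gene AT4G16260 111-fold lower (61.6 to 222). WRKY75 (AT5G13080), a transcription factor gene, had 3 reads at low CO2 and was 155-fold lower (52.6 to 752).

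The next question was whether genes homologous to those of the C4 cycle were higher at low CO2 in this C3 leaf. The C4 cycle homologues went both ways: of 23 counted members 3 were at least 2-fold higher, 2 at least 2-fold lower and 18 within 2-fold. The 3 higher members were PCK1 (phosphoenolpyruvate carboxykinase), 3.10-fold higher (2.98 to 3.23), the plastid dicarboxylate transporter gene DIT1, 2.99-fold higher (2.86 to 3.12), and the aspartate aminotransferase gene ASP1, 2.68-fold higher (2.48 to 2.90). The 2 lower members were PPC1, a phosphoenolpyruvate carboxylase gene, at 62.3 and 25.6 RPKM and 2.43-fold lower (2.3 to 2.57), and PPDK (pyruvate orthophosphate dikinase), at 276 and 129 RPKM and 2.15-fold lower (2.1 to 2.21). PPDK came to lie just inside 2-fold after median scaling. PPC2, the more abundant carboxylase gene, was at 140 and 171 RPKM, a ratio of 1.22 (1.19 to 1.26). The malic enzyme genes NADP-ME2 and NADP-ME4 had ratios of 0.730 (0.712 to 0.748) and 1.93 (1.87 to 2.00). The median log2 ratio of the list, 0.10, lay at the 87.1 percentile of 10000 random lists matched on expression, a description of these columns only. With no filter on low values it was -0.023 at the 57.0 percentile, and after quantile normalization 0.21 at the 90.4 percentile.

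Of the carbonic anhydrases, which interconvert CO2 and bicarbonate, a pair was much higher at low CO2. CA1, the plastid beta carbonic anhydrase, was at 264 RPKM at normal CO2 and 2272 RPKM at low CO2, 8.60-fold higher (8.39 to 8.82), and CA2 was 5.17-fold higher (5.0 to 5.33). These were the only members of 7 counted to reach 2-fold, and none was 2-fold lower. BCA4 (131.6 and 248 RPKM) and BCA3 (12.5 and 9.39 RPKM), named after their values were seen, lay within 2-fold. The list median of 0.51 lay at the 97.1 percentile of random lists, inside the central 95%. It passed the 97.5 percentile without a filter on low values (97.9) and after quantile normalization (97.7).

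Photorespiration genes lay mostly within 2-fold. Of 25 counted members of the pathway, which recovers carbon after Rubisco fixes oxygen, 2 were at least 2-fold higher, 2 at least 2-fold lower and 21 within 2-fold. The glycolate oxidase gene GOX2 was 2.48-fold higher (2.43 to 2.53) and AT1G32470, listed as a subunit of glycine decarboxylase, 2.08-fold higher (2.00 to 2.16). GGT2, a glutamate glyoxylate aminotransferase gene, was 2.09-fold lower (1.98 to 2.2) and the transporter gene AT4G22840 2.14-fold lower (1.88 to 2.44). All but GOX2 of these members lay within 2-fold under some alternative, GGT2 and AT4G22840 under both scalings (GGT2 at -0.98 and -0.95 on the log2 scale) and AT1G32470 after removal of the GC content and coding length trend (0.99). Among the always reported members, SHM1 (serine hydroxymethyltransferase) had a ratio of 1.87 (1.85 to 1.89), GS2 (plastid glutamine synthetase) 1.90 (1.87 to 1.94), HPR1 (hydroxypyruvate reductase) 1.07 (1.05 to 1.09) and GLDP1 (glycine decarboxylase P protein) 0.618 (0.612 to 0.625). The list median of 0.28 lay at the 97.5 percentile, just above the 0.28 that bounds the central 95% of random lists. It lay inside that range with a pseudocount of 0.1 (97.3), with genes of at least 5 RPKM (93.0) and after quantile normalization (78.0).

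**Figure D2:**
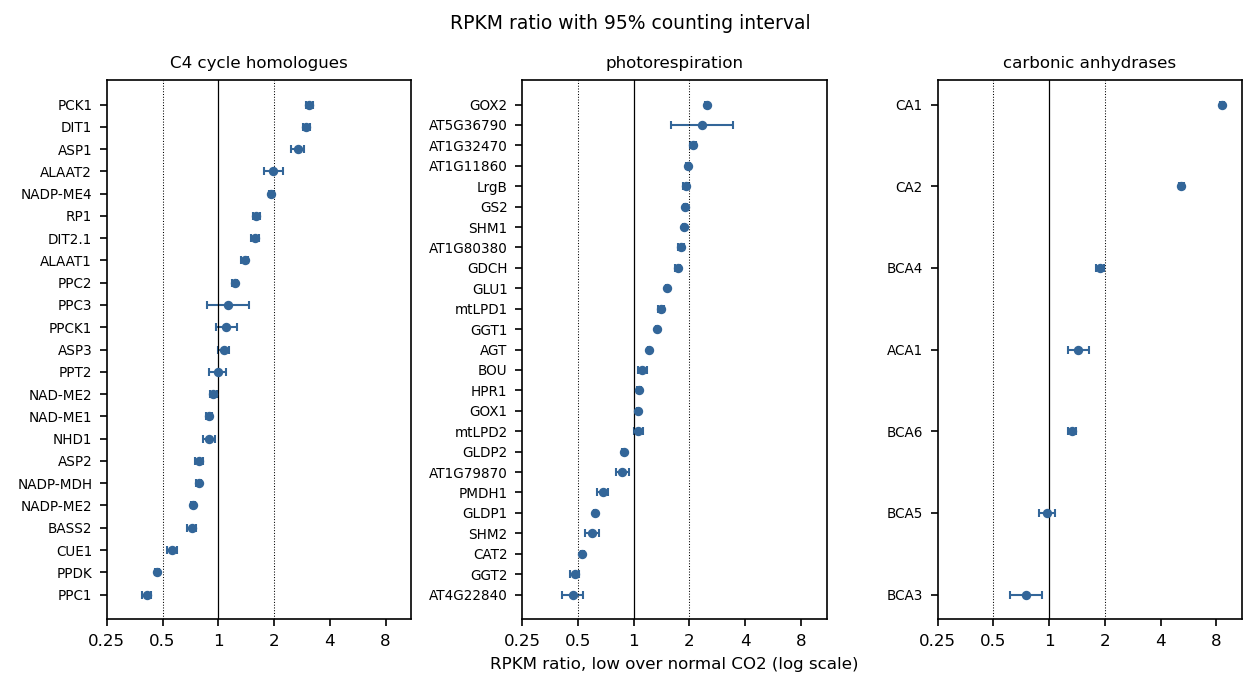
RPKM ratio of low over normal CO2 on a log axis for the counted C4 cycle homologues, photorespiration genes and carbonic anhydrases (points), with 95% intervals that cover counting error only, a solid line at equal values and dotted lines at a 2-fold difference. CA1 (8.60) and CA2 (5.17) have the highest ratios, and PPC1 (0.411) is the lowest of the C4 cycle homologues.

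Genes of the Calvin-Benson cycle and of the light reactions were higher at low CO2 as groups. Of 24 counted Calvin-Benson genes 7 were at least 2-fold higher and 1, the transketolase gene TKL2 (6.46 and 2.34 RPKM, named after its values were seen), at least 2-fold lower, with 16 within 2-fold. Genes of the Rubisco small subunit led the list, with RBCS2B 9.32-fold higher (9.11 to 9.54), RBCS1B 8.24-fold higher (7.98 to 8.51) and RBCS3B 4.55-fold higher (4.48 to 4.61). RBCS1A, the most abundant of them, was at 10462.5 and 24998.5 RPKM, 2.39-fold higher (2.37 to 2.4), but within 2-fold after quantile normalization (0.90 on the log2 scale). These genes have near-identical copies whose reads can be split by counting, so single values are uncertain. Their summed reads took 0.698% of the depth at normal CO2 and 2.17% at low CO2, 3.11-fold higher (3.10 to 3.13). CP12-2, a regulator of the cycle, was 2.78-fold higher (2.70 to 2.85), whereas RCA (Rubisco activase) had a ratio of 1.1 (1.09 to 1.1). The list median of 0.65 lay at the 99.98 percentile.

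Of 43 counted genes of light harvesting and photosystems 9 were at least 2-fold higher, none at least 2-fold lower and 34 within 2-fold, with a median of 0.70 at the 99.99 percentile (0.42 after quantile normalization). The ferredoxin NADP reductase gene FNR2 was 2.80-fold higher (2.74 to 2.87) and ATPD, the delta subunit of the plastid ATP synthase, 2.66-fold higher (2.56 to 2.75). LHB1B1 was 4.02-fold higher (3.83 to 4.21) and LHCB2.3 2.52-fold higher (2.44 to 2.59), both from families of similar copies. Summed over copies, the ratio was 1.52 (1.51 to 1.53) for the 5 LHCB1 genes and 1.01 (1.00 to 1.03) for the 3 LHCB2 genes. Among 16 counted genes of cyclic electron flow only PPL2 reached 2-fold, at 2.28-fold higher (2.16 to 2.41), and the median of 0.38 lay at the 98.9 percentile. The circadian clock list, described further on, also lay above random lists in these columns.

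**Figure D3:**
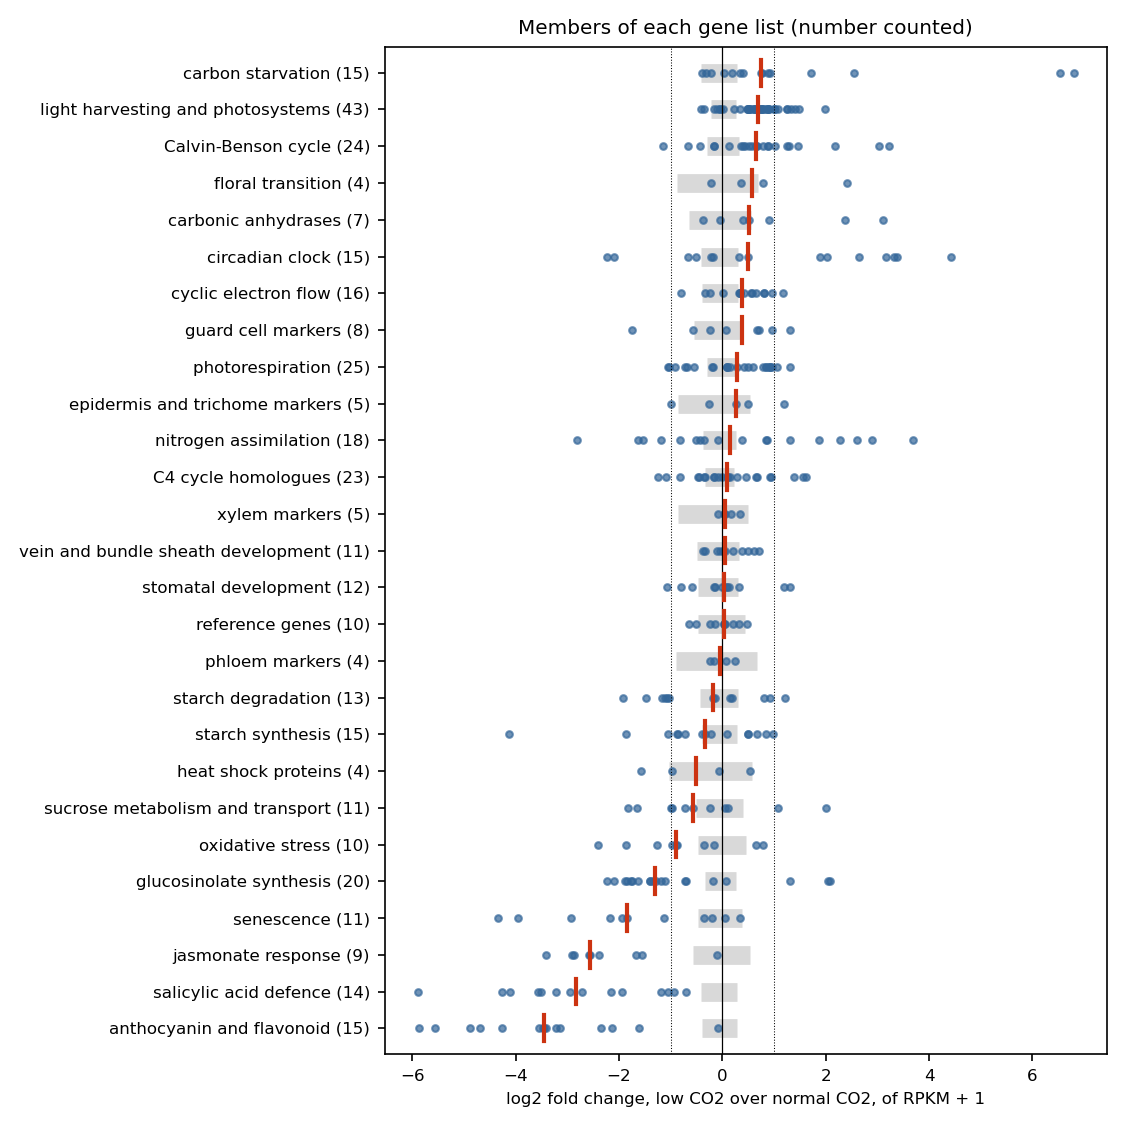
Log2 ratio of low over normal CO2, of RPKM + 1, for the counted members of 27 gene lists (blue points, number counted in brackets), with the list median as a red bar, the central 95% of medians of 10000 random lists as a grey bar, and dotted lines at a 2-fold difference. The anthocyanin list has the lowest median (-3.45) and the carbon starvation list the highest (0.75).

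Carbon metabolism beyond the Calvin-Benson cycle differed in both directions. The carbon starvation list had 4 of 15 counted members at least 2-fold higher, none at least 2-fold lower and 11 within 2-fold, and its median of 0.75 lay above all 10000 random lists (percentile 100). With no filter on low values the median was 0.39, at the 99.9 percentile. Besides DIN10 and BT2 these were SEN1, at 30.7 and 185 RPKM and 6.03-fold higher (5.43 to 6.70), and the asparagine synthetase gene ASN1, 8.19-fold higher (5.16 to 13.6) from 21 reads at normal CO2. ASN1 lay within 2-fold with a pseudocount of 5, as any gene below 5 RPKM in both columns must. In starch synthesis 3 of 15 members were at least 2-fold lower and none higher. The glucose 6-phosphate transporter gene GPT2 was at 75.2 and 3.34 RPKM, 22.5-fold lower (18.1 to 28.3), the granule-bound starch synthase gene GBSS1 3.68-fold lower (3.56 to 3.81) and APL3, of ADP-glucose pyrophosphorylase, 2.1-fold lower (1.97 to 2.23), though APL3 lay within 2-fold under both scalings. The median of starch synthesis, -0.34, lay at the 4.95 percentile, inside the central 95%.

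Starch degradation had 6 of 13 members at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.17 at the 25.3 percentile. The disproportionating enzyme gene DPE2 was 3.88-fold lower (3.70 to 4.07), the beta-amylase gene BAM1 2.80-fold lower (2.67 to 2.93) and the isoamylase gene ISA3 2.28-fold lower (2.16 to 2.41), while the beta-amylase gene BAM3 was 2.32-fold higher (2.26 to 2.37). With genes of at least 5 RPKM this list lay at the 0.700 percentile. In sucrose metabolism and transport 2 of 11 members were at least 2-fold higher and 2 at least 2-fold lower. The sucrose efflux transporter genes SWEET12 and SWEET11 were 4.06-fold (3.82 to 4.31) and 2.11-fold higher (2.05 to 2.18), and the sucrose synthase gene SUS3 was 3.71-fold lower (3.17 to 4.36) and AT1G62660, listed as a vacuolar invertase, 4.13-fold lower (3.53 to 4.85). The median of -0.58 lay at the 1.54 percentile, and moved inside the central 95% without a filter (3.28) and with a pseudocount of 5 (3.08).

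Nitrogen assimilation genes went both ways. Of 18 counted members 6 were at least 2-fold higher, 4 at least 2-fold lower and 8 within 2-fold, so that the median of 0.14 lay at the 88.7 percentile (-0.22 at the 13.4 percentile for the 16 genes of at least 5 RPKM). The nitrate reductase gene NIA1 was at 13.8 and 190.5 RPKM, 13.8-fold higher (12.9 to 14.7), and the nitrite reductase gene NIR1 7.63-fold higher (7.24 to 8.04). GLT1, the NADH-dependent glutamate synthase, was 6.5-fold higher (6.21 to 6.80). The glutamate dehydrogenase gene GDH3 was 15.3-fold lower (9.74 to 25.3), with 20 reads at low CO2. The cytosolic glutamine synthetase genes GLN1.1 (1073 and 344 RPKM) and GLN1.3 (57.1 and 24.6 RPKM) and the glutamate synthase gene GLU2 (33.2 and 10.9 RPKM), named after their values were seen, made up the other lower members.

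Anthocyanin, defence and senescence genes were lower at low CO2 as groups. In the anthocyanin and flavonoid list 14 of 15 counted members were at least 2-fold lower and none higher, with a median of -3.45 below all 10000 random lists (percentile 0). Chalcone synthase (CHS) was at 1148 and 43.5 RPKM, 26.4-fold lower (24.9 to 28.0), and DFR (dihydroflavonol reductase) 32.0-fold lower (28.6 to 35.9). TTG1 (86.6 and 81.6 RPKM), named after its values were seen, was the member within 2-fold. F3H, another step of the pathway singled out after its values were seen, was listed at 0.183 RPKM at normal CO2 and at 0 at low CO2, values far below those of CHS and DFR on both sides of it, and was not counted.

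In the salicylic acid defence list 12 of 14 members were at least 2-fold lower and none higher, with a median of -2.83 at percentile 0. Besides PR1, PAD3, of camalexin synthesis, was 29.1-fold lower (22.5 to 38.3) and PBS3 16.2-fold lower (13.2 to 20.1). FMO1, a gene of systemic acquired resistance, had 2 reads at low CO2 and was 302-fold lower with an interval of 83.2 to 2496. In the jasmonate list 8 of 9 members were at least 2-fold lower and none higher, with a median of -2.56 at percentile 0. The transcription factor gene MYC2 was 11.2-fold lower (10.3 to 12.1), the synthesis gene OPR3 7.65-fold lower (7.31 to 8.01), and the repressor genes JAZ10 and JAZ1 7.71-fold (6.63 to 9.0) and 6.03-fold lower (5.70 to 6.39).

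Of 11 senescence genes 7 were at least 2-fold lower, none higher and 4 within 2-fold, with a median of -1.85 at percentile 0. SAG13 was at 474 and 22.5 RPKM, 21.0-fold lower (18.9 to 23.5), SAG12, a cysteine protease gene of late senescence, 97.9-fold lower (38.0 to 361) with 4 reads at low CO2, and the transcription factor genes NAP and WRKY53 7.75-fold (7.23 to 8.32) and 4.91-fold lower (4.18 to 5.80). The oxidative stress list had 3 of 10 members at least 2-fold lower and none higher, with a median of -0.89 at the 0.110 percentile. These were BAP1, 7.60-fold lower (4.97 to 12.1), the zinc finger gene ZAT10, 3.73-fold lower (3.40 to 4.09), and the iron superoxide dismutase gene FSD1, 2.41-fold lower (2.33 to 2.5). Of 4 counted heat shock genes HSP70 was 6.37-fold lower (4.18 to 10.1) and the others lay within 2-fold. HSP70, below 5 RPKM in both columns, had to come within 2-fold with a pseudocount of 5. The list median was -0.52 at the 13.8 percentile. That median was -0.029 at the 52.2 percentile over the 3 genes left after removal of the GC content and coding length trend.

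Glucosinolate synthesis genes were mostly lower, with 13 of 20 members at least 2-fold lower, 3 at least 2-fold higher and a median of -1.31 at percentile 0. The near-identical copies CYP79F1 and CYP79F2, which start the aliphatic branch, were 4.76-fold (4.55 to 4.97) and 5.22-fold lower (4.32 to 6.34), uncertain as single genes, and their summed reads had a ratio of 0.209 (0.20 to 0.218). The higher members did not act in synthesis of the core structure: the myrosinase genes TGG1 and TGG2, whose products break glucosinolates down, were 4.14-fold (4.06 to 4.23) and 4.24-fold higher (4.1 to 4.38). The third was MYB28, a regulator of the aliphatic branch named after its values were seen, at 113 and 280 RPKM.

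Circadian clock genes differed in both directions and widely. Of 15 members 7 were at least 2-fold higher, 2 at least 2-fold lower and 6 within 2-fold, with a median of 0.50 at the 99.8 percentile, which was 1.2 over genes of at least 5 RPKM. PRR5 was at 1.3 and 48.0 RPKM, 37.0-fold higher with no interval because its reads were not recovered. ELF4 was 11.8-fold higher (8.62 to 16.6), the glycine-rich RNA binding protein gene GRP7 10.5-fold higher (10.2 to 10.9) and RVE1 9.58-fold higher (8.59 to 10.7). The lower members, LNK1 (100.2 and 20.7 RPKM) and PRR9 (6.58 and 0.781 RPKM), were named after their values were seen. The hour of harvest was not given in the sources used here. Of 4 floral transition genes FT, the mobile flowering signal, was 5.97-fold higher (4.78 to 7.52) and the others lay within 2-fold, with a median of 0.58 at the 95.7 percentile.

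Markers of leaf cell types and of leaf anatomy gave no list outside the central 95% of random lists. All 11 genes of vein and bundle sheath development lay within 2-fold, with a median of 0.04 at the 71.4 percentile, including the chloroplast regulators GLK1 (ratio 0.770, 0.742 to 0.798) and GLK2 (ratio 1.63, 1.55 to 1.72). Over the 7 of them with at least 5 RPKM the median was 0.39 at the 95.6 percentile, and over all 11 after quantile normalization 0.22 at the 78.1 percentile. Among 12 stomatal development genes STOMAGEN was 3.14-fold higher (1.77 to 5.85) and SPCH 5.81-fold higher (2.91 to 12.8), from 17 and 10 reads at normal CO2, and the receptor kinase gene ER was 2.25-fold lower (2.02 to 2.51). All 3 lay within 2-fold with a pseudocount of 5, as did ER under both scalings. For SPCH, below 5 RPKM in both columns, that pseudocount allowed no other outcome. The list median of 0.03 lay at the 67.8 percentile. Of 8 guard cell markers the potassium channel gene GORK was 3.10-fold higher (2.55 to 3.77), within 2-fold with a pseudocount of 5, and the anion channel gene ALMT12 4.32-fold lower (3.45 to 5.46), with a median of 0.37 at the 97.4 percentile, which was 0.073 at the 73.1 percentile for the 7 genes of at least 5 RPKM.

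All 4 phloem markers and all 5 xylem markers lay within 2-fold, with medians of -0.04 (49.8 percentile) and 0.05 (68.4 percentile). The sucrose transporter gene SUC2 and the proton pump gene AHA3 of the phloem had ratios of 0.851 (0.831 to 0.870) and 0.892 (0.870 to 0.914), and the xylem protease genes XCP1 and XCP2 ratios of 1.31 (1.04 to 1.65) and 1.13 (0.987 to 1.3). Of 5 epidermis and trichome markers PDF1 was 3.53-fold higher (2.2 to 5.86) and the others lay within 2-fold. PDF1, below 5 RPKM in both columns, had to come within 2-fold with a pseudocount of 5. The list median was 0.26 at the 87.0 percentile (-0.25 for the 3 genes of at least 5 RPKM). All 10 reference genes lay within 2-fold. Their median was 0.03 (61.1 percentile) and their mean -0.05, with UBQ10 at a ratio of 0.701 (0.694 to 0.707) and ACT2 at 1.25 (1.22 to 1.27).

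Across the 27 lists 6 lay above the 97.5 percentile and 7 below the 2.5 percentile. Random draws of genes would put 1.35 lists outside. Members of a pathway can vary together, so that number is no expectation for these lists. The lists above were carbon starvation, light harvesting, Calvin-Benson, clock, cyclic electron flow and photorespiration. Those below were anthocyanin, salicylic acid defence, jasmonate, senescence, glucosinolate, oxidative stress and sucrose.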

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

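Size rules of 1.5-fold and 4-fold, the filters on reads, intervals and nuclear genes, the removal of the GC content and coding length trend and the restriction to genes with both properties were chosen after seeing the data. No paired analysis was possible because the table holds no columns of single replicates. For the same reason the planned replicate block, eBayes without trend or robust, leaving out each replicate, camera with an estimated correlation, fry and the adjusted p with a fold threshold were not run. Over the pseudocounts, filters and scalings set beforehand the genes at least 2-fold higher numbered 674 to 1217 and those lower 1175 to 2096, the 1175 coming with a pseudocount of 5, which shrinks ratios of low genes. A size rule of 1.5-fold gave 2244 higher and 3312 lower genes, and one of 4-fold 243 and 525. Quantile normalization moved the median log2 ratio of all counted genes by 0.11, to 0.05, and median scaling by 0.10.

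The median of the C4 cycle homologues, 0.10, was -0.023 with no filter and 0.21 after quantile normalization. The photorespiration median, 0.28, was 0.33 with no filter, 0.22 at a mean of at least 5 RPKM, 0.12 after quantile normalization and 0.38 after median scaling. The Calvin-Benson median, 0.65, was 0.60, 0.75 and 0.61 after quantile normalization, median scaling and removal of the trend. The carbon starvation median, 0.75, was 0.39 with no filter, the clock median, 0.50, was 1.2 at a mean of at least 5 RPKM, and the light harvesting median, 0.70, was 0.42 after quantile normalization. Among lists inside the central 95%, medians ranged over the alternatives from 0.073 to 0.49 for guard cells, 0.024 to 0.39 for veins, -0.68 to -0.029 for heat shock, -0.22 to 0.29 for nitrogen, -0.25 to 0.45 for epidermis, -0.60 to -0.073 for starch degradation, -0.34 to -0.23 for starch synthesis, 0.021 to 0.25 for xylem and 0.36 to 0.68 for floral transition. Beyond the different gene sets and the shifts just given, the cause was not tested. All 13 lists that stood apart kept the sign of their median under the 7 alternatives run on lists. Of these lists 11 stayed outside the same bound under every one, photorespiration and sucrose being the exceptions. Median scaling shifts a list and its random lists alike, so its percentiles could not differ from the main ones. The median changed sign under at least 1 alternative in 6 lists inside the central 95%: C4 homologues, nitrogen, stomatal development, phloem, epidermis and reference genes. Heat shock genes gave no value at a mean of at least 5 RPKM. All named genes that passed the 2-fold rule, 90 in the main setting, kept their direction wherever an alternative counted them. Of these 13 came inside 2-fold under at least 1 alternative: 9 with a pseudocount of 5, 5 after quantile normalization, 5 after median scaling and 3 after removal of the trend. The pseudocount of 5 took in ASN1, STOMAGEN, SPCH, GORK, PDF1, HSP70, ER, APL3 and AT4G22840. For ASN1, SPCH, PDF1 and HSP70, below 5 RPKM in both columns, this was bound to happen whatever their ratio. Both scalings took in GGT2, AT4G22840, APL3 and ER, with RBCS1A under quantile normalization and PPDK under median scaling, and the trend took in AT1G32470, GGT2 and APL3. Depth limits genes with few reads: a gene of 1 kb below 0.118 RPKM at normal CO2 rests on under 3 reads.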

Other observations

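The gene families in the next 2 paragraphs and 4 of the tests that follow were chosen after the values were seen. A family chosen in that way can stand apart from random lists for that reason alone, so its percentile lends no support. The tests of GC content and coding length and of the hour of harvest were written before their results were seen. Nuclear families were gathered by product name, so members named otherwise are missing, such as WRKY53 among the WRKY genes.

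Expansin genes, which loosen the cell wall, and SAUR genes, a family of early auxin response, were higher as families at low CO2. Of 14 counted expansin genes 5 were at least 2-fold higher and 2 at least 2-fold lower, with a median log2 ratio of 0.72 (99.99 percentile of random lists), and EXPA1 stood at 49.0 and 1067 RPKM, 21.8-fold higher. Of 45 SAUR genes 19 were at least 2-fold higher and 2 lower (median 0.65, percentile 100), with AT2G21210 at 3.75 and 74.0 RPKM. Of 16 xyloglucan endotransglucosylase genes, which remodel the cell wall, 6 were higher, 2 lower and 8 within 2-fold, and their median of 0.11 lay inside the range of random lists (85.8 percentile); XTH4 was at 23.2 and 249 RPKM and XTH24 at 430 and 122 RPKM. Of 21 B-box genes 7 were higher and 3 lower, with a median of -0.02 (55.6 percentile); CO, a promoter of flowering, was at 1.24 and 45.9 RPKM and BBX29 at 23.4 and 4.46 RPKM. The 33 counted plastid-encoded genes had a median of 0.56 (percentile 100), with ATCG00490 at 593 and 1376 RPKM. Plastid-encoded genes took 0.883% of summed RPKM at normal CO2 and 1.15% at low CO2. Their reads were not recovered, so no counting interval could be given. A difference between library preparations cannot be told apart from one in expression. The 17 mitochondrion-encoded genes had a median of -0.11, which was 0.01 after quantile normalization.

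Families tied to defence, some of whose members also stand in the lists above (JAZ1, JAZ10, WRKY70 and GSTF12), held more lower than higher genes. Of 24 cysteine-rich receptor-like kinase genes 13 were at least 2-fold lower and none higher (median -1.10, percentile 0), with CRK10 at 130 and 12.9 RPKM. Of 10 JAZ genes, repressors of jasmonate responses, 7 were at least 2-fold lower and 1 higher, with JAZ7 at 68.7 and 1.96 RPKM and JAZ4 at 1.01 and 3.21 RPKM. Of 34 WRKY genes 14 were lower and 3 higher (median -0.72), with WRKY46 at 93.4 and 5.73 RPKM and WRKY7 at 6.31 and 30.9 RPKM. Of 42 glutathione S-transferase genes 16 were lower and 1 higher (median -0.68), and of 54 TIR-NBS-LRR resistance genes 13 were lower, 1 higher and 40 within 2-fold (median -0.43). Over the 51 TIR-NBS-LRR genes with a GC content and coding length the median was -0.22 at the 3.12 percentile, inside the central 95% of random lists, and after removal of the trend -0.12 at the 19.0 percentile. All 45 counted genes gathered by name as cytosolic ribosomal proteins lay within 2-fold. The expansin, SAUR, receptor kinase, JAZ, WRKY and transferase families stood apart from random lists on the same side after quantile normalization. They also did so after removal of the GC content and coding length trend. Both were run on the same 2 columns and the same chosen families, so they bear on the processing only. Median scaling shifts a family and its random lists alike, so it could not change the percentiles.

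The anthocyanin, salicylic acid, jasmonate and senescence lists were lower together, with 47 of 49 members below 0 and a combined median of -2.71. Median scaling moves all genes by the same 0.10, so it left the median at -2.61. It shows only that a common shift of that size was too small to give the pattern. Removal of a trend over GC content and coding length left -2.66. A lower share of epidermis in the low CO2 leaves would have lowered its markers alike, yet their median was 0.26 (SD 0.82 over 5 genes, of which PDF1 had 24 reads at normal CO2), and over the 3 of at least 5 RPKM it was -0.25, with the lowest, CER5, at -0.99. An aberrant plant or library behind the normal CO2 column may be the source and cannot be told apart from the CO2 level, because the table holds 0 columns of single replicates. The CO2 level itself stays open, untested, and so does the hour of harvest, which the next paragraph takes up.

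Clock genes differed between the columns in both directions. A later hour of harvest of the low CO2 leaves is a candidate explanation: of 6 evening-phased genes outside the clock list 5 were above 0 (median 1.68), FKF1 and PRR3 among them, and of 7 morning-phased genes 3 were (median -0.72), with LNK3 and CDF3 lower. The difference of 2.4 exceeded all 10000 random pairs of lists, whose 97.5 percentile was 0.79, although the evening-phased CKB4 (ratio 0.839) and the morning-phased COL2 (4.89) went the other way. Outside the phase lists the evening gene GI (ratio 0.581) and the dawn genes RVE1 and RVE2 (9.58-fold and 45.5-fold higher) also went against the pattern of higher evening and lower morning genes. A clock phase shifted by CO2 could give such values too, as could an aberrant plant or library behind either column, so these hypotheses all remain. The hour may also bear on other genes, among them NIA1, CA1, BT2, FT and the photosynthesis genes. It may likewise bear on carbon starvation genes such as DIN10 of the dark-inducible set, and on the anthocyanin, salicylic acid, jasmonate and senescence lists. None of this was tested.

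The RBCS genes and the photosynthesis lists were higher together. A different assignment of reads among near-identical RBCS copies would leave their sum level, yet the summed reads were 3.11-fold higher at low CO2. That holds only if reads shared by copies were kept, and the way reads were counted was not given. A trend over GC content and coding length would take the combined median of the Calvin-Benson and light harvesting lists toward 0, yet over 67 genes it went from 0.66 to 0.62. The CO2 level, an aberrant plant or library and, from the clock test above (2.4), the hour of harvest remain as possible explanations. These columns do not separate them.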
